A study of Mus musculus with 14 samples.

How the data were processed

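RNA of sorted mouse HSCs was measured on 14 Agilent-026655 arrays: 6 from control bone marrow, 4 from spleens after 7 days of G-CSF and 4 from spleens 14 days after Pten deletion. Groups were taken from the labels. The labels name Cy3 as the label while the labelling protocol names a Cy5-type dye, and the scans hold the red channel only, which was used as it is. Per the file headers, the processed signal is an intensity made by Agilent Feature Extraction 11.5.1.1, with the background subtracted, spatial trends removed and surrogate values in place of dim spots, and with no normalization between arrays. The flags for spots well above background, saturated or irregular are other values, of 0 or 1, per the file headers. The deposited value table holds log2 values whose columns have nearly the same distribution: each has a median of 8.55, the sorted values of columns differ by at most 0.0089, and the lowest correlation of a column with the log2 signal of its array is 0.9944. How this table was made is not stated. It served as an alternative only.

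Spots marked as non-uniform or population outliers were left out (0.293% to 0.616% of the 43020 spots of an array), and no spot was saturated. The log2 processed signal was centred on the 75th percentile of the array, and spots of a probe were averaged, which left 418 missing probe values. Of 39429 probes, 27655 were named by accession through a gene table of assembly GRCm38.p6, used for names only, 3396 carried a current symbol, and 8378 kept the name in the files. Coordinates are those of the files, in build mm9. Probes well above background on at least 4 of 14 arrays were kept (29016), and the probe with the highest mean over all arrays stood for its gene, which left 22882 genes, 4937 of them with more than 1 such probe. Where no array of a group was well above background, a fold is given as a lower limit ("at least"). The number of arrays limits the precision.

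Limma 3.58.1 in R 4.3.3 was fitted to all 14 arrays with a coefficient per group (11 residual degrees of freedom, prior 3.89), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were Pten-deficient spleen against control marrow, G-CSF spleen against control marrow, and Pten-deficient against G-CSF spleen. Each of 33 gene lists, fixed before the data were examined, was tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list. The mean of a list's members per array, as a difference from the control mean, is its score, compared by exact permutation. Exact permutation tests were two-sided; their smallest p is 0.00476 for 4 arrays against 6 and 0.0286 for 4 against 4. Files were read with jsonlite 2.0.0 and the R package data.table (1.17.8), and figures were drawn with Python 3.11.15.

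The genes named were chosen by a rule fixed before the data were examined. For each comparison it takes Pten and Csf3r, the 6 largest increases and 6 largest decreases among called genes with a gene symbol whose groups do not overlap, up to 3 called members of each of the 6 lists with the lowest camera p, and Cxcr4, Itga4, Kit, Cdkn1c, Mki67, Ccnd1, Foxo3 and Hlf. Genes named as passing an adjustment over a list alone, or under an alternative, and Gp9, Cavin2, Csf2rb2 and Bgn, were chosen after their values were seen where the rule does not name them.

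Other choices, fixed in advance, changed the background correction, scaling, filter, choice of probe, spread model, array weights, groups in the fit, slide, scan day, replicate number and controls used, and left out each array in turn. A block for title style, a covariate for the share of spots above background, leaving out slide 4 and the permutation of list scores were added after the data were seen. The steps were tested on simulated data of 22718 genes with 100 changed at each size. A log2 change of 1 was recovered for 44% of the changed genes between Pten-deficient and control arrays, 37% between G-CSF and control arrays and 31% between the spleen groups, and a change of 2 for 90%, 89% and 90%. Each comparison gave 9 false calls and no list was falsely called. Genes were simulated independently of one another. The simulation therefore does not show how often lists are falsely called when genes are correlated, as in the real arrays. To ask how much of the likeness of the 2 comparisons with controls comes from the controls they share, 100 simulations of unchanged groups and 20 splits of the controls were run; the use of these splits for the 98 genes with the lowest p was added after the data were seen.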

Results

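Gene expression was measured on 14 one-colour Agilent mouse arrays, each hybridised with RNA of sorted haematopoietic stem cells (HSCs), the rare blood-forming cells that give rise to all blood lineages. The sort took cells positive for CD150, Kit and Sca1 and negative for CD48 and lineage markers, from mice of 8 to 10 weeks of age. Control HSCs came from bone marrow (6 arrays), Pten-deficient HSCs from spleen 14 days after deletion (4 arrays), and G-CSF HSCs from the spleens of mice given granulocyte colony-stimulating factor, a cytokine that drives HSCs out of the marrow, for 7 days (4 arrays). Pten encodes a lipid phosphatase that opposes PI3K-AKT signalling. By its title the series concerns how loss of Pten mobilises HSCs and whether this passes through G-CSF, so the comparisons set each kind of spleen HSC against control marrow HSCs and against each other. The design has no control spleen, so tissue and treatment go together in both comparisons with control marrow. Sample titles come in a short style (controls 1 to 4 and the 4 G-CSF arrays) and a longer one (controls 5 and 6 and the 4 Pten-deficient arrays), and the labels do not say whether these are separate experiments. The labels do not say that the samples of a group came from separate animals, and p-values measure the spread between these samples.

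Between 58.1% and 75.9% of the 43020 spots on an array lay well above background, and the 75th percentile of the processed signal ran from 869 to 2138 intensity units. Arrays of a group correlated over genes with r from 0.932 to 0.982. The arrays did not all match their own group best. Controls 3 to 6, G-CSF replicates 1 and 3 and Pten-deficient replicates 1 and 4 had their best match in another group (r from 0.971 to 0.979). The first principal component held 37.2% of the variance and followed the share of spots above background over the 14 arrays (Pearson r = 0.824, permutation p = 0.00041; Spearman rho = 0.811, permutation p = 0.00065). This r was 0.869 without the 2 arrays farthest from the median share and 0.680 within the 6 controls. The number of arrays limits the precision of every value given here, and 1 array, labelled control 5, had 75.6% of its spots above background while the other controls had 58.1% to 72.2%.

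Pten itself was read by a probe at chromosome 19, 32892510 to 32894351 (build mm9), with the sequence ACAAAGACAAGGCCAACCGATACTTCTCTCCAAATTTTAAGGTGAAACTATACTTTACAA. Its level, as log2 signal relative to the 75th percentile of the array, was 0.35 ± 0.38 (SD, n = 6) in the controls, 0.18 ± 0.13 (SD, n = 4) in the G-CSF arrays and -0.29 ± 0.08 (SD, n = 4) in the Pten-deficient arrays. The difference of the Pten-deficient arrays from the controls was -0.64 ± 0.19 log2 units (SE). It did not pass limma's test over all genes (adjusted p = 0.458), and it had a two-sided exact permutation p of 0.0333 over 210 arrangements for this probe alone. Against the G-CSF arrays the difference was -0.47, with all 4 Pten-deficient arrays below all 4 G-CSF arrays (exact permutation p = 0.0286, the smallest that 70 arrangements allow). That difference did not pass limma's test over all genes either (adjusted p = 0.421). The array labelled control 5 had a Pten level of -0.37, inside the Pten-deficient range of -0.39 to -0.20, while the other 5 controls lay between 0.23 and 0.63. Without that array the difference from the controls was -0.78 (limma adjusted p = 0.0754). Within slides that held both groups the difference was -0.77 on slide 1 and -0.81 on slide 3, and 0.08 on slide 4, which held the array labelled control 5; with slide as a block it was -0.53 (limma adjusted p = 0.459). With the style of the sample title as a block, which leaves controls 5 and 6 to carry the comparison, it was -0.22 (limma adjusted p = 0.977). Over all the alternatives tried the adjusted p ran from 0.0231, with array weights, to 0.99. Which part of Pten was deleted is not given in the sources used here, so this probe may lie outside it and then checks no label. A second probe above background on all arrays, at 32899714 to 32899773, gave -0.28 against the controls (exact permutation p = 0.119), and a probe at 32883442 to 32883501 lay above background on only 4 arrays, with -0.53 (exact permutation p = 0.219). Against the G-CSF arrays these probes gave -0.12 and -0.40 (exact permutation p = 0.657 and 0.343).

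**Figure D1:**
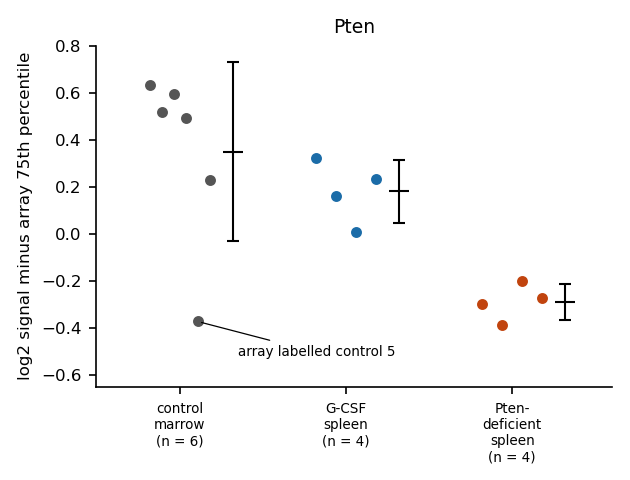
Pten signal per array, as log2 processed signal minus the 75th percentile of the array (vertical axis), in control marrow, G-CSF spleen and Pten-deficient spleen HSCs. Points are arrays, and bars give the mean and SD; the Pten-deficient arrays lie between -0.39 and -0.20, and the array labelled control 5 lies among them at -0.37.

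HSCs from Pten-deficient spleens carried more transcript of interferon-stimulated genes than control marrow HSCs. The members of this list, which respond to interferon and include antiviral effectors, were higher by a mean of 0.47 log2 units, with 48 of 50 measured members positive. Genes of mitosis were higher by a mean of 0.70 log2 units (38 of 39 positive) and genes of DNA replication by 0.31 (38 of 41 positive), calls that were lost with an estimated correlation (adjusted p = 0.163 each). Immediate-early genes, which cells induce within minutes of stimulation or tissue dissociation, were lower by a mean of -0.80 log2 units, with 1 of 36 members positive, a call that was lost with an estimated correlation (adjusted p = 0.163) and with title style as a block (adjusted p = 0.448). The G-CSF and STAT3 list, which holds receptor and signalling genes beside response genes, was also lower, at a mean of -0.24 (8 of 33 positive). Dendritic cell markers were higher at 0.32 (15 of 20 positive).

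No gene passed limma's test between Pten-deficient and control arrays: 0 of 22879 genes had an adjusted p under 0.05, the smallest being 0.115, and 1410 genes had an unadjusted p under 0.05. Other choices of the fit gave more genes changed, Pten-deficient spleen against control bone marrow: 320 genes with array weights, 62 with slide as a random block, 7 after normexp background correction, 4 with a trend in the variance and 6 against the 4 controls titled Ctrl_BM.

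Of the 50 interferon genes, 10 were higher when p was adjusted over the list alone, against 0 over all genes tested, and none was lower. Ifi27l2a had a difference of 1.41 ± 0.22 log2 units (SE; -0.21 ± 0.18 in 4 Pten-deficient arrays, -1.61 ± 0.42 in 6 controls, SD; limma adjusted p over the list alone = 0.000468). Irf7, a transcription factor that amplifies the interferon response, had 1.30 ± 0.25, and the antiviral oligoadenylate synthetase Oas2 had 1.24 ± 0.20. The list was called by camera (adjusted p = 5.04e-19) and held with an estimated correlation (adjusted p = 0.0303). Its score did not overlap between the groups (exact permutation p = 0.00476, the smallest that 4 arrays against 6 allow; 0.105 after adjustment over 33 lists). The call was kept under each of the 31 alternatives run for this list, with means from 0.40 to 0.53. With slide as a block the mean was 0.46, and within the 3 slides that held both groups it was 0.33, 0.34 and 0.76.

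Camera called 13 of the 33 lists between Pten-deficient and control arrays, 5 higher and 8 lower, and 3 of these held with an estimated correlation. The other 2 that held were the G-CSF and STAT3 list (camera adjusted p = 8.19e-05; adjusted p = 0.0475 with an estimated correlation) and the dendritic cell list (camera adjusted p = 0.00165; adjusted p = 0.0475 with an estimated correlation). In the dendritic cell list 2 members, the MHC class II genes H2-Eb1 (1.27 ± 0.35) and H2-Ab1 (0.86 ± 0.25), were higher when adjusted over the list alone, against 0 over all genes tested. No member of the G-CSF and STAT3 list passed either adjustment. This list's mean within slides was -0.31 and -0.33 on slides 3 and 4 but 0.10 on slide 1, and -0.18 with slide as a block. The slide 1 value rests on 1 array of each group. Pten-deficient replicate 4 had the highest score of its group (-0.06), and control 4 the lowest of the controls (-0.16). With title style as a block the call of the G-CSF and STAT3 list ended at a mean of -0.25 (adjusted p = 0.0583), and that of the dendritic cell list at 0.13 (adjusted p = 0.133).

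The calls of the cell cycle and immediate-early lists were lost with an estimated correlation, at an adjusted p of 0.163 each for mitosis, DNA replication and the immediate-early genes. Mitotic scores were 0.69 ± 0.23 (SD, n = 4) in the Pten-deficient arrays and 0.00 ± 0.50 (SD, n = 6) in the controls, and the proliferation marker Mki67 had a difference of 0.62 ± 0.32 (limma adjusted p = 0.857). No member of either cell cycle list passed an adjustment. Within slides 1, 3 and 4 the mitotic mean was 0.20, 1.12 and 0.51, and the DNA replication mean 0.12, 0.50 and 0.23. Of the immediate-early genes, 2 were lower when adjusted over the list alone, against 0 over all genes tested: Klf4, at least 2.15-fold lower, and Maff, at least 1.45-fold lower, both not well above background on any Pten-deficient array. The immediate-early score ranged widely in the controls, from -1.17 on control 6 to 0.82 on control 1, against -0.9996 to -0.48 in the Pten-deficient arrays (exact permutation p = 0.0571), and within slides it was -0.89, -0.86 and -0.93. With title style as a block the immediate-early call ended, at a mean of -0.22 (adjusted p = 0.448), while the mitotic and DNA replication lists kept theirs.

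The remaining called lists shifted by under 0.25 log2 units, and none held with an estimated correlation. PI3K-AKT pathway genes had a mean of -0.18 (camera adjusted p = 0.000115; adjusted p = 0.163 with an estimated correlation), and FoxO targets, normally induced when AKT is inactive, -0.21 (0.000139; adjusted p = 0.09 with an estimated correlation). HSC identity genes had -0.17 (3.74e-05; adjusted p = 0.163 with an estimated correlation), with Hlf at -0.53 ± 0.23 and Kit at -0.35 ± 0.17, neither past limma's test (adjusted p = 0.78 and 0.825). Quiescence genes had -0.15 (0.0198; adjusted p = 0.163 with an estimated correlation), with Cdkn1c at -0.41 ± 0.30 (limma adjusted p = 0.98). Oxidative phosphorylation genes had 0.19 (3.74e-05; adjusted p = 0.478 with an estimated correlation), with -0.02 within slide 1. Sterol synthesis genes had -0.12 (0.0115; adjusted p = 0.619 with an estimated correlation), with 0.05 within slide 4, and ribosomal protein genes -0.06 (0.0164; adjusted p = 0.792 with an estimated correlation), with 0.10 within slide 1. With title style as a block the oxidative phosphorylation call was kept, the PI3K-AKT, FoxO and HSC identity calls ended, and the sterol, ribosomal and quiescence means changed sign, to 0.05, 0.09 and 0.02. Genes of retention, adhesion and homing were not called, with a mean of 0.06 where camera's direction was down, and a camera adjusted p of 0.878. Within that list, Cxcr4, the receptor that holds HSCs in the marrow, had 0.08 ± 0.27 and the integrin gene Itga4 0.10 ± 0.21. Csf3r, which encodes the G-CSF receptor, had 0.01 ± 0.19, and its sign changed with the scaling. Foxo3 had -0.15 ± 0.21 and Ccnd1, which encodes cyclin D1, 0.03 ± 0.19.

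**Figure D2:**
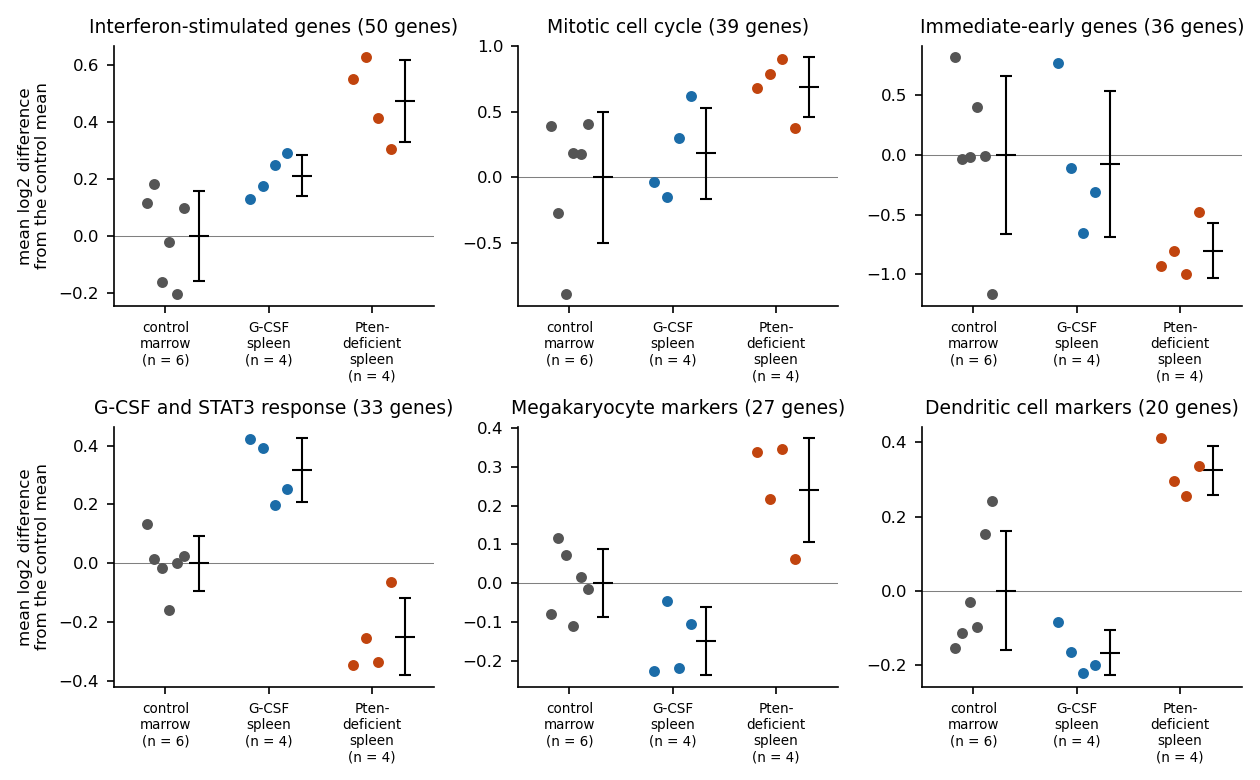
Score per array of 6 gene lists, as the mean over the list's genes of the log2 difference from the control mean (vertical axis), in control marrow, G-CSF spleen and Pten-deficient spleen HSCs. Points are arrays, and bars give the mean and SD; interferon scores are 0.30 to 0.63 in the Pten-deficient arrays and -0.21 to 0.18 in the controls, and G-CSF and STAT3 scores are 0.20 to 0.42 in the G-CSF arrays and -0.34 to -0.06 in the Pten-deficient arrays.

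G-CSF spleen HSCs differed from control marrow HSCs in 98 genes, among them Cd53, Selp, Csf2rb, Pim2, Pf4, H2-Eb1 and Ccnd1. Cd53, a leukocyte tetraspanin, rose by 3.83 ± 0.56 log2 units (SE), from -2.43 ± 1.17 (SD, n = 6) to 1.40 ± 0.19 (SD, n = 4), and Selp, which encodes the adhesion receptor P-selectin, rose by 3.02 ± 0.52. The cytokine signalling genes Csf2rb, the shared beta chain of several cytokine receptors, and the kinase gene Pim2 rose by 1.503 ± 0.28 and 1.45 ± 0.24. Pf4, a chemokine gene of megakaryocytes and of part of the HSCs, fell by 2.57 ± 0.37, and the MHC class II gene H2-Eb1 fell by 2.11 ± 0.35. Ccnd1 fell by 1.47 ± 0.19, from 0.34 ± 0.27 (SD, n = 6) to -1.13 ± 0.05 (SD, n = 4).

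Limma's test called 98 of 22881 genes, 50 higher and 48 lower, and 80 of them differed at least 2-fold. Besides Cd53 and Selp, the largest increases with groups that did not overlap were in Wfdc17, which encodes a secreted protease inhibitor (3.09 ± 0.40), the lipoprotein receptor gene Vldlr (2.87 ± 0.37) and the matrix protein gene Tgfbi (2.84 ± 0.34). Pla2g7, a phospholipase gene, was at least 2.23-fold higher, not being well above background on any control. The largest decreases included the transcriptional co-repressor gene Runx1t1 (-2.01 ± 0.29). Defb35, Mlph and Cfc1 were not well above background on any G-CSF array and were at least 2.03-fold, 2.81-fold and 1.74-fold lower. Adjusted p-values of the genes named here ran from 0.00278 to 0.0418. With scan day as a block, which leaves 2 G-CSF arrays to carry the comparison, 4 genes were called and none of the named genes kept its call, with differences of 3.93 for Cd53 (adjusted p = 0.0939), -2.10 for Pf4 (adjusted p = 0.115) and -1.51 for Ccnd1 (adjusted p = 0.0591); the called genes named here kept their signs, at adjusted p-values of 0.0591 to 0.158. No slide held a G-CSF array with another group; with slide as a random block 40 genes were called, with median scaling 60, and with only these groups in the fit 57. The count was 64 without control 1 or control 2, 61 without control 3, and 62, 42 and 36 without G-CSF replicate 1, 2 or 3.

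Camera called 6 lists between G-CSF and control arrays, 3 higher and 3 lower, and none held with an estimated correlation. The G-CSF and STAT3 list shifted higher by a mean of 0.32 (21 of 33 positive; camera adjusted p = 0.0272; adjusted p = 0.244 with an estimated correlation), and its score did not overlap between groups (exact permutation p = 0.00476; 0.157 after adjustment over the lists). Csf2rb and Pim2 were its 2 members called over all genes, and 8 were higher when adjusted over the list alone, among them Socs3 (1.72 ± 0.53) and Cebpd (1.29 ± 0.40). Interferon genes shifted higher by 0.21 (34 of 50 positive; camera adjusted p = 0.00649; adjusted p = 0.437 with an estimated correlation), where Oas2 rose by 1.72 ± 0.20 as the only member called over all genes, and 5 were higher when adjusted over the list alone. These were Oas2, Ifi27l2a (1.07 ± 0.22), Oas3, Irf7 (0.96 ± 0.25) and Rtp4. All of them were also among the 10 that passed this way between Pten-deficient arrays and the same controls. Progenitor markers of the multipotent and lymphoid-primed stages shifted by 0.31 (camera adjusted p = 0.0294, and adjusted p = 0.244 with an estimated correlation), with Wfdc17 higher and Mn1 lower (-1.97 ± 0.35). Mn1 was well above background on only 1 of 4 G-CSF arrays and Wfdc17 on 2 of 6 controls. With scan day as a block, which leaves 2 G-CSF arrays to carry the comparison, the calls of these 3 lists ended at means of 0.32, 0.23 and 0.298 (adjusted p = 0.234, 0.12 and 0.291), while 8 lists were called lower and none higher. The number of lists called was 3 without control 3, 2 without control 4, 10 without control 5, 13 without control 6, 3 without G-CSF replicate 4 and 10 without Pten-deficient replicate 2.

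Lower lists in the G-CSF arrays were ribosomal protein genes at -0.17 (camera adjusted p = 0.000146; adjusted p = 0.733 with an estimated correlation), oxidative phosphorylation genes at -0.14 (0.022; adjusted p = 0.733 with an estimated correlation) and sterol synthesis genes at -0.20 (0.0332; adjusted p = 0.733 with an estimated correlation). With scan day as a block these 3 calls were kept and their means lay farther from 0, at -0.36 (adjusted p = 6.37e-14), -0.24 (adjusted p = 1.83e-05) and -0.26 (adjusted p = 0.00354). In the sterol list the lipoprotein receptor gene Ldlr fell by 1.05 ± 0.20, and 4 members were lower when adjusted over the list alone, including the enzyme gene Lss (-1.10 ± 0.30). Megakaryocyte markers were not called as a list (mean -0.15, camera adjusted p = 0.0514), with 1 member called higher and 3 lower. Of the fixed genes besides Ccnd1 none passed limma's test. Kit had -0.59 ± 0.17 and Foxo3 -0.74 ± 0.21 (adjusted p = 0.196 each), Cdkn1c -0.69 ± 0.30, Hlf -0.60 ± 0.23, Cxcr4 -0.40 ± 0.27, Itga4 -0.29 ± 0.21, Csf3r 0.11 ± 0.19 and Mki67 0.36 ± 0.32. A second Mki67 probe gave -0.26.

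Between the spleen groups, HSCs from Pten-deficient mice carried more transcript of Pf4 and of 3 MHC class II genes than HSCs from spleens of G-CSF-treated mice. They carried less of Pim2 and Csf2rb, members of the G-CSF and STAT3 list. Pf4 was higher by 4.18 ± 0.41 log2 units (SE), at 2.47 ± 0.81 (SD, n = 4) against -1.70 ± 0.63 (SD, n = 4). The MHC class II genes H2-Eb1, H2-Aa and H2-Ab1, which lie together on chromosome 17, were higher by 3.37 ± 0.38, 2.35 ± 0.30 and 2.06 ± 0.27. Pim2 was lower by -1.93 ± 0.26 and Csf2rb by -1.89 ± 0.31. Ccnd1 was higher by 1.5 ± 0.21.

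Limma's test called 51 of 22878 genes between the spleen groups, 24 higher and 27 lower in the Pten-deficient arrays, of which 50 differed at least 2-fold. The other leading increases were in the tubulin gene Tuba8 (2.75 ± 0.29) and the acetylcholinesterase gene Ache (1.96 ± 0.29). The leading decreases were in the imprinted non-coding RNA Meg3 (-3.67 ± 0.53), Wfdc17 (-3.50 ± 0.44), Vldlr (-3.03 ± 0.40), Tgfbi (-2.12 ± 0.38), the pantetheinase gene Vnn1 (-1.98 ± 0.38) and the lactate dehydrogenase gene Ldhd (-1.94 ± 0.37). Adjusted p-values of these genes ran from 0.000882 to 0.0495. A second Vldlr probe gave -0.82. Wfdc17 and Vnn1 were each well above background on only 1 of 4 Pten-deficient arrays, so the sizes of their differences are uncertain. Pten-deficient replicate 4 lay nearest to the G-CSF arrays in Wfdc17, Tgfbi, Meg3 and Ldhd, and without it 100 genes were called. Title style goes with the spleen groups, so a difference between the styles is in each of these values, and only the controls, 4 of one style and 2 of the other, hold both; with title style as a block, which rests on them, 2 genes were called, Vldlr and Pf4. The count was 32 without Pten-deficient replicate 1 or 3, 17 with only these groups in the fit, and 16 with scan day as a block, under which Pf4, H2-Eb1, H2-Aa, Tuba8 and Wfdc17 kept their calls. The calls of the other named genes ended there, with differences of -3.13 for Vldlr, 1.99 for Ache and -1.91 for Pim2 (adjusted p = 0.0508 each), 1.54 for Ccnd1 (0.0542), 1.94 for H2-Ab1 and -2.41 for Vnn1 (0.0612 each), -3.37 for Meg3 (0.0934), -1.59 for Csf2rb (0.196), -1.905 for Ldhd (0.213) and -1.76 for Tgfbi (0.248).

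**Figure D3:**
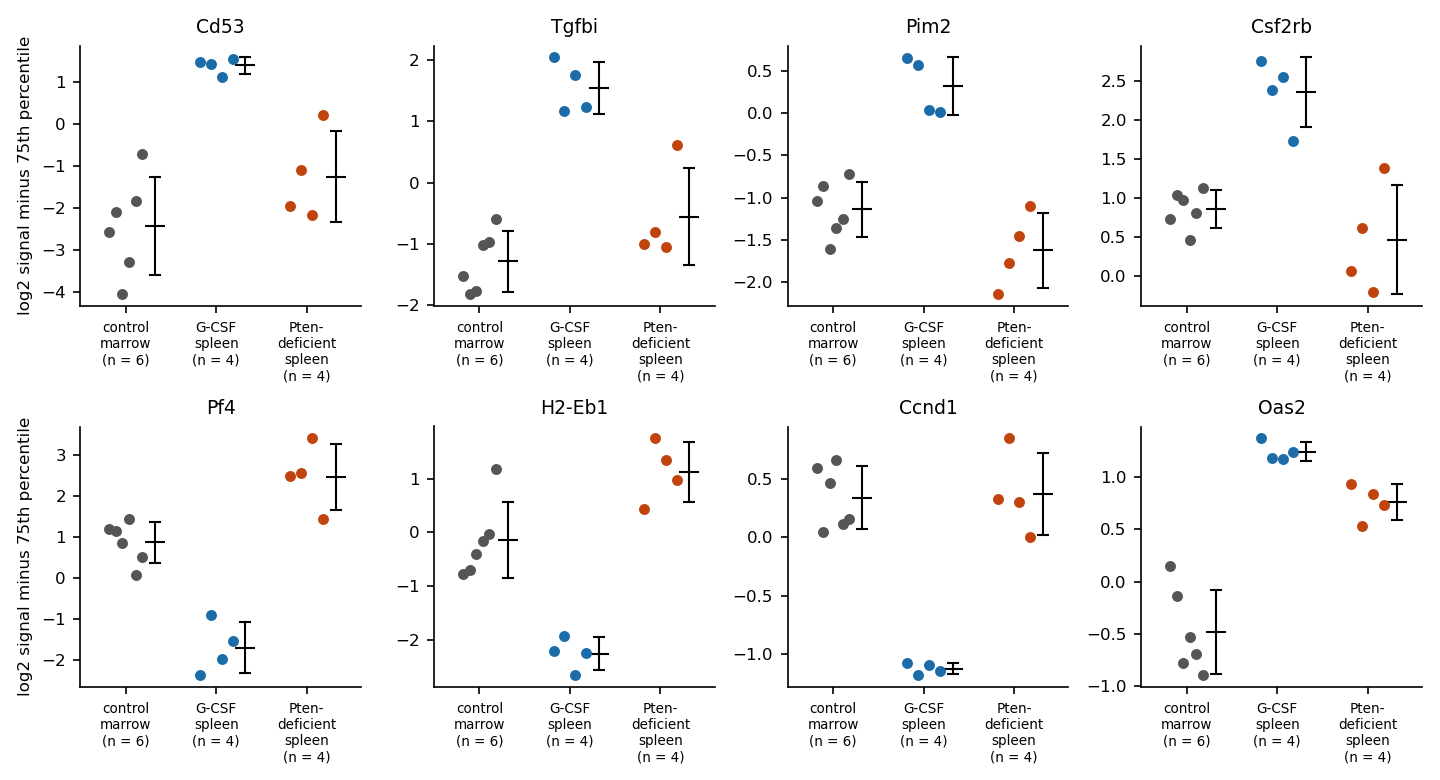
Signal per array of 8 genes, as log2 processed signal minus the 75th percentile of the array (vertical axis), in control marrow, G-CSF spleen and Pten-deficient spleen HSCs. Points are arrays, and bars give the mean and SD; Pf4 lies between -2.38 and -0.92 in the G-CSF arrays and between 1.43 and 3.41 in the Pten-deficient arrays, and Tgfbi of Pten-deficient replicate 4 stands at 0.62.

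Camera called 12 lists between the spleen groups, 6 higher and 6 lower in the Pten-deficient arrays, and 1 held with an estimated correlation. That list was the G-CSF and STAT3 response, lower by a mean of -0.56 (9 of 33 positive; camera adjusted p = 2.16e-07; adjusted p = 0.0157 with an estimated correlation). Pim2 and Csf2rb were called over all genes, and 8 members were lower when adjusted over the list alone, among them the feedback inhibitor gene Socs3 (-2.76 ± 0.59) and Pim1 (-1.32 ± 0.35). Megakaryocyte markers were higher by a mean of 0.39 and a median of 0.06 (camera adjusted p = 0.00237; adjusted p = 0.0793 with an estimated correlation). Pf4, Gp9 (1.38 ± 0.20) and Cavin2 (1.59 ± 0.23) were called over all genes, and over the list alone 6 members were higher and 1, Selp, was lower (-1.66 ± 0.57). Dendritic cell markers were higher by a mean of 0.49 and a median of 0.196, with 11 of 20 positive (camera adjusted p = 0.0366, and adjusted p = 0.128 with an estimated correlation). The 3 called members were the MHC class II genes, and over the list alone 7 were higher and 1 was lower.

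Oxidative phosphorylation genes were higher by 0.33 in the Pten-deficient arrays (58 of 61 positive; camera adjusted p = 3.49e-08; adjusted p = 0.357 with an estimated correlation). Mitotic genes were higher by 0.51 (1.15e-05; adjusted p = 0.478 with an estimated correlation) and DNA replication genes by 0.35 (1.15e-05; adjusted p = 0.352 with an estimated correlation). Interferon genes were higher by 0.26 (36 of 50 positive; 0.000922; adjusted p = 0.352 with an estimated correlation), with Tap1 (1.13 ± 0.23) and Igtp (0.98 ± 0.25) passing when adjusted over the list alone and 0 over all genes. Immediate-early genes were lower by -0.73 (2 of 36 positive; 5.11e-07; adjusted p = 0.394 with an estimated correlation), with 3 members passing over the list alone, and with title style as a block the mean changed sign to 0.15. Progenitor markers were lower by -0.42 (0.000866; adjusted p = 0.0672 with an estimated correlation), and mast cell and basophil markers by -0.40 (0.0061; adjusted p = 0.0993 with an estimated correlation), where Csf2rb2, a cytokine receptor gene that HSCs also express, was the called member (-1.92 ± 0.26). Stromal markers were lower by -0.26 (0.0208; adjusted p = 0.0993 with an estimated correlation), with Bgn called higher (1.34 ± 0.19) and Sparc, Col4a2 and Vim lower over the list alone. Inflammatory NF-kB genes were lower by -0.15 (0.0248; adjusted p = 0.0993 with an estimated correlation). With scan day as a block the progenitor, mast cell, stromal and NF-kB calls ended, at means of -0.41, -0.41, -0.36 and -0.11 (adjusted p = 0.0538, 0.0541, 0.0642 and 0.338). The other 8 calls were kept, and ribosomal protein genes, not called without the block (mean 0.115, camera adjusted p = 0.0558), were called higher at 0.305 (adjusted p = 1.59e-09). MYC targets and NRF2 genes, not called without the block either (camera adjusted p = 0.182 and 0.248), were called higher at 0.173 and 0.212 (adjusted p = 0.00883 and 0.0292). Cxcr4 (0.49 ± 0.30), Itga4 (0.38 ± 0.22), Kit (0.23 ± 0.18), Cdkn1c (0.28 ± 0.33), Mki67 (0.27 ± 0.35), Foxo3 (0.59 ± 0.23), Hlf (0.07 ± 0.26) and Csf3r (-0.11 ± 0.21) did not pass limma's test.

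Whether the Pten and G-CSF arrays moved away from the controls in the same genes was tested over the genes measured in both comparisons. No gene was called in both, since no gene was called between Pten-deficient and control arrays. Of the 98 genes called for G-CSF, 37 were also called between the spleen groups, a comparison that uses the same G-CSF arrays. In the Pten-deficient arrays 70 of the 98 differed from the controls with the same sign, 26 of them at an unadjusted p under 0.05, against 8 with the opposite sign at that p, and the median ratio to the G-CSF difference was 0.196, all with the same controls on both sides. The Pten-deficient arrays were not alike in such genes. On a scale from the controls (0) to the G-CSF arrays (1), replicate 4 lay at 0.507 and the others at 0.0317 to 0.0879. Much of the ratio may therefore come from replicate 4, and it was not computed without that array. With separate controls, 3 to pick the 98 genes with the lowest p for G-CSF and the other 3 for the Pten-deficient arrays, a mean of 49.3 of 98 had the same sign over 20 splits of the controls (range 28 to 63), with a mean median ratio of -0.0018. The differences from the controls correlated across genes with r = 0.297, against a mean of 0.397 (range -0.681 to 0.894) in 100 simulations of unchanged groups set against the same controls, and genes are not independent replicates. The covariance was 0.0386 against a simulated 0.0461, a difference of -0.0075. With the controls split so that each comparison had its own 3, the correlation had a mean of 0.00552 over 20 splits (range -0.323 to 0.191). At an unadjusted p under 0.05, 252 genes moved the same way in both comparisons, 119 higher and 133 lower. The simulations gave a mean of 238 with a wide range of 0 to 3048, and independent lists would share 43.4 and 34.8.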

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

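The tests of the slide and of a wrong label for Pten-deficient replicate 4, the interferon score of control 5 and the interferon tests were chosen after the results were seen.

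The spleen groups differed in 51 genes and in the G-CSF and STAT3 response list, whose mean was -0.557 log2 units in the Pten-deficient arrays relative to the G-CSF arrays. No other of the 35 splits of these 8 arrays gave more than 1 gene, and 1 split, the real one, gave as many as 51. This argues against chance for the count of called genes but does not exclude it. A share of 1 in 35 is the smallest these splits allow, and several counts were tested this way. A difference between the title styles is not excluded by these splits, since the real split is also that of the styles; with title style as a block, which rests on the controls, the count was 2. At an unadjusted p under 0.05, 6 of 35 splits gave as many as the real 2565, up to 4899. Chance cannot be excluded for the 12 lists, since 5 of 35 splits gave as many, up to 15. Between G-CSF and control arrays 4 of 100 splits, the real one included, gave at least the 98 genes observed, a share under 5 in 100 by 1 split. These 100 were drawn from 210 arrangements, so the share is an estimate, and it lies too near 5 in 100 to exclude chance for this count. Chance cannot be excluded for the count at an unadjusted p either. The other 3 gave 178, 1207 and 3307 genes, and at that p, under 0.05, 17 of 100 splits gave as many genes as the real one (2544), up to 7514. The split with 3307 genes put control 5, control 6, G-CSF 2 and G-CSF 4 in the same group. Their shares of spots above background, 75.6%, 72.2%, 69.0% and 75.9%, were the highest of the arrays compared, and the next was control 1 at 68.1%. That split therefore follows the share of spots above background, a structure of the samples that such counts can reflect. The 6 lists of that comparison were reached by 58 of 100 splits (highest other 19). Between Pten-deficient and control arrays the count of 0 genes tests nothing, as 100 of 100 splits must reach it (highest other 9). At an unadjusted p under 0.05, 22 of 100 splits gave as many genes as the real 1410, up to 4282. The 13 lists were reached by 19 of 100 (highest other 17), so chance cannot be excluded for that count. These splits exchange arrays freely between slides, while the correlation within slides was 0.546, and the splits that gave 9 and 4 genes kept control 5 and Pten-deficient 1, which share slide 4, together. Both arrays also had the highest shares of spots above background in that comparison, 75.6% and 75.4%. With slide as a random block the real groups gave 62 genes and 13 lists, and no splits were drawn within slides.

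Of 165 groups of values examined, 5 held an array far from the others, a smaller share than the about 1 in 20 that chance gives. This count therefore sets none of them apart from chance. Pten-deficient replicate 4 stood apart in Tgfbi, at 0.6204 against -1.06 to -0.8017 in the others of its group, and in Meg3, at 0.4369 against -2.452 to -2.002. G-CSF replicate 2 had a DNA replication score of -0.2889, Pten-deficient replicate 1 a PI3K-AKT score of -0.2544, and control 3 a 75th percentile of the signal of 869.4.

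Pten-deficient replicate 4 stood toward the G-CSF arrays over the genes called between G-CSF and control, at a position of 0.507 from the controls (0) to the G-CSF arrays (1), while the other Pten-deficient arrays lay at 0.0317 to 0.0879. The slide it shares with control 4 is argued against, as control 4 lay at -0.0152, and so is a mislabelled G-CSF array, as its position between the spleen groups was 0.495 against 0.869 to 0.919 for the G-CSF arrays. A mixture with 37% G-CSF spleen RNA may account for it: over 105 genes its residual was 0.377, or 1.05 times that of the other 3 arrays, against 0.854 without mixing and 0.468 for an equal fraction of every log2 difference. Gene values of this array had been looked at before that test was written. A subset of cells with a G-CSF-like state would give the same mixture, and a biological source was not tested.

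The array labelled control 5 had a Pten level of -0.37, which differed from the mean of the other controls by -0.865. In a test written beforehand its position from the controls (0) to the Pten-deficient arrays (1) was 0.803 over 711 genes, inside the 0.46 to 0.865 of the Pten-deficient arrays and above the -0.135 to 0.459 of the other controls, as a Pten-deficient array would give. With brightness as a covariate it lay at 0.675, still inside the Pten-deficient range of 0.512 to 0.848 and above controls 1, 2, 4 and 6 (-0.123 to 0.427), while control 3 moved from 0.224 to 0.897 (interquartile range 1.32). Its interferon score was -0.205, against 0.304 to 0.6254 (SD 0.143) in the Pten-deficient arrays, unlike the other 4. That list was chosen for its low p with control 5 counted among the controls, so its score here is not an independent test. The list's call was kept without control 5. This score and the position point opposite ways, so a wrong label is not decided. Brightness is argued against, as its slope gives -0.0804 (interval -0.23 to 0.0693). Control 5 shares slide 4 with Pten-deficient 1, and each was the best match of the other (r = 0.979). It also has the longer title style, and control 6, of that style too, lay at 0.459. Slide and title style could give the same position and were not tested for it. Loss of Pten in a marrow sample stays open and was not tested.

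Interferon-stimulated genes were higher in the Pten-deficient arrays than in the controls by a mean of 0.47. The slide is argued against, since the smallest shift within a slide was 0.326, above the controls' SD of 0.157. The spleen as the whole cause cannot be told apart from loss of Pten: there is no control spleen, the G-CSF arrays stood at 0.21 themselves, and although the scores of the spleen groups did not overlap (exact permutation p = 0.0286, the smallest possible, and 0.105 adjusted over the lists), the gap between them was 0.0126, under the SDs of 0.0726 and 0.143, and the list's call between them was lost with an estimated correlation (adjusted p = 0.352). Cells of other types cannot be told apart from a response of the HSCs, because the largest of 6 marker shifts, 0.324 for dendritic cells, and that of NK cells, 0.273, lie between what they would need and what would exclude them; the gate removes lineage-positive cells, 20 of 23 dendritic and 10 of 18 NK markers were tested, 2 and 1 are in another list, and the brightest were Siglech (5.32 in controls, 5.34 in Pten-deficient arrays) and Ciita (3.59 and 3.46), and Prf1 (2.82 and 2.74) and Nkg7 (1.38 and 2.45). Loss of Pten stays open. How Pten was deleted is not given in the sources used here, so an effect of that procedure cannot be told apart from loss of Pten.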

How the results depend on the processing

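The title style block, the brightness covariate (share of spots above background) and the omission of slide 4 were chosen after the data were seen; the cause of the moves below was not tested.

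The interferon list between Pten-deficient and control arrays and the G-CSF and STAT3 list between the spleen groups kept their calls under every alternative run for them (31 and 30), with means of 0.402 to 0.5299 and -0.6207 to -0.4658. Between the spleen groups Pf4 and H2-Eb1 kept theirs under the 26 alternatives run gene by gene, at 3.698 to 4.522 and 2.765 to 3.604. With title style, where genes were only counted, Pf4 and Vldlr were called and H2-Eb1 was not. The permutation of list scores is not counted among these alternatives, and after adjustment it called 0 lists in each comparison. For the G-CSF and STAT3 list between the spleen groups its adjusted exact permutation p was 0.105.

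For genes changed, Pten-deficient spleen against control bone marrow, the count was 7 with normexp, 4 with a variance trend, 320 with array weights, 62 with slide as a random block, 6 with the 4 Ctrl_BM controls and 1 without slide 4 (Tceanc2). It stayed at 0 by limma's test against the 2 controls titled WT, with 1155 genes at an unadjusted p under 0.05. For genes changed, G-CSF spleen against control bone marrow, it was 60 with median scaling, 156 with array weights, 57 with only these groups, 40 with slide as a random block, 4 with scan day, 14 with the replicate block and 190 with the brightness covariate. For genes changed, Pten-deficient spleen against G-CSF spleen, it was 98 with normexp, 81 with the filter at 10 arrays, 93 with a variance trend, 284 with array weights, 17 with only these groups, 16 with scan day, 2 with title style and 110 with the brightness covariate. Scan day and the replicate block leave fewer arrays to carry a comparison.

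Lists called with an estimated correlation numbered 3, 0 and 1 in the order Pten-deficient against control, G-CSF against control and Pten-deficient against G-CSF, and 8, 18 and 19 with title style; the replicate block gave 18 for G-CSF. Of the alternatives run, Pten expression by group passed the threshold with array weights only, at -0.7033, and was -0.2169 with title style. Genes shared by the comparisons with controls numbered 2 with normexp (Ebi3 and Oas2), 3 with a variance trend (these and Ifi27l2a), 13 with array weights and 4 with slide as a random block (Col18a1, Endod1, Oas2 and Runx1t1).

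The sign of Csf3r, Pten against control, reversed with quantile normalization (-0.05213), median scaling (-0.01171), the deposited table (-0.05262), and slide as a random (-0.03969) or fixed block (-0.06433). Mki67, G-CSF against control, reversed with scan day (-0.1444). Title style reversed the sterol (0.05073), ribosomal (0.09177) and quiescence (0.02081) lists between Pten-deficient and control arrays and the immediate-early list between the spleen groups (0.1513).

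Leaving out each array gave 0 to 1 genes between Pten-deficient and control arrays (1 without control 5, Tceanc2, or Pten-deficient 3) and 11 to 18 lists. For G-CSF against control it gave 36 to 106 genes (64 without control 1 or 2, 61 without control 3, 62, 42 and 36 without G-CSF 1, 2 or 3) and 2 to 13 lists (3 without control 3, 2 without control 4, 10 without control 5, 13 without control 6, 3 without G-CSF 4, 10 without Pten-deficient 2). Between the spleen groups it gave 32 to 100 genes (32 without Pten-deficient 1 or 3, 100 without Pten-deficient 4) and 11 to 15 lists. Pten expression by group ran from -0.7825 to -0.5816, and 0 genes were shared throughout. Signs changed for ribosomal proteins, Pten against control (-0.1241 to 0.03407), Csf3r (-0.1186 to 0.099), Cxcr4 (-0.03852 to 0.245) and Ccnd1 (-0.1275 to 0.1549) between the same groups, Csf3r, G-CSF against control (-0.01124 to 0.2064), and Mki67 (-0.05763 to 0.4651) and Hlf (-0.05958 to 0.1865) between the spleen groups.

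Array weights ran from 0.35 for G-CSF 1 to 3.64 for Pten-deficient 3, with 0.391 for control 5. Signal over background limits the rest: 6856 of 39429 probes were well above background on no array.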

Other observations

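Selp, Pf4 and H2-Eb1 are genes that the rule set beforehand names; setting them side by side, and H2-Ab1 against the controls, was chosen after their values were seen.

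The megakaryocyte genes Selp and Pf4 moved apart in the G-CSF arrays. Relative to control marrow, Selp, an adhesion receptor of platelets and activated endothelium, was higher in the G-CSF arrays by 3.02 log2 units while Pf4 was lower by -2.57. In the Pten-deficient arrays Pf4 stood at 2.47 against 0.87 in the controls, with 1.43 to 3.41 over the arrays, and did not pass limma's test against the controls. The MHC class II genes H2-Eb1 and H2-Ab1 stood at -0.14 and 0.19 in the controls and were lower in the G-CSF arrays, at -2.25 and -1.01. In the Pten-deficient arrays their means were 1.13 and 1.05, but these arrays overlapped the controls and neither gene passed limma's test against them (adjusted p = 0.364 and 0.406).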
